A study of Saccharomyces cerevisiae with 20 samples.

How the data were processed

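PAT-seq libraries of Saccharomyces cerevisiae were analysed, 10 from the wild-type strain and 10 from the strain lacking SET1. Per the labels, cells grew at 30 °C in rich medium, were arrested with 5 µg/ml α-factor for about 2 h until at least 95% were unbudded, were washed free of the pheromone, and were sampled at 15 min intervals. Per the labels, 1 µg of total RNA entered each library and reads were 150 nt long. Groups and time points were taken from the sample labels, and all columns of the tables were matched to samples by name.

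The authors deposited a table of read counts per feature, which are whole numbers and were used as raw counts. They also deposited a table of counts of reads with a poly(A) tail, and a table of the mean tail length in nucleotides over those reads. The submitters' processing notes name Bowtie2 2.2.5, Bowtie and the build sacCer3 without giving their roles. The counting tool, its annotation, its strand setting and its filters were not given in the sources used here. A mean tail length multiplied by its number of poly(A) reads was whole, within a tolerance of 1e-06, for 99.998% of values. No count of poly(A) reads exceeded the read count of its feature.

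Of 6532 features, 5861 matched 1 gene symbol of the reference annotation of assembly R64, 70 matched several genes and 601 matched none, so these keep the identifier of the deposited table. Coordinates and strands come from that annotation. Features of several genes, Ty elements and paralogous genes may share reads and are uncertain. Features without reads numbered 119.

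Read counts were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling) in R 4.3.3 on genes with a mean count of at least 10. The strain difference used all 20 libraries with time point as a factor of 10 levels. Changes over time used the 18 libraries after release and a natural spline of time with 5 degrees of freedom per strain. The difference of profiles was the F-test of the strain-by-spline terms in the same fit. P-values were adjusted by the Benjamini-Hochberg method, and genes were called at an adjusted p below 0.05. Log2 differences are set1Δ minus WT, and the range of a gene over time is that of log2 CPM between its lowest and highest library after release. CPM used TMM-scaled library sizes.

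Each strain was grown as 1 culture, and each time point gave 1 library per strain. The p-values therefore measure how far a difference stood out from its spread between time points, and cover neither the spread between cultures nor a repeat of a library.

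Tail lengths were tested with limma 3.58.1 (empirical Bayes, robust, trend) on values from at least 10 poly(A) reads, for genes with at least 8 values in each strain. The median tail length over genes with at least 10 poly(A) reads in every library was compared by an exact two-sided sign-flip permutation test over the 10 time points, with 1024 sign patterns. The smallest p it can give is 0.002.

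The timing of gene lists was described by the mean z-score of log2(CPM + 1). The lag was sought from −30 to 30 min in steps of 2.5 min on linearly interpolated profiles, and a negative lag means that set1Δ came first. The arrest was described by log2(CPM + 1) at 0 min minus the asynchronous culture. List medians were placed among those of 10000 random lists of equal size and similar expression.

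In all, 21 gene lists were fixed: COMPASS subunits, G1/S, histone, G2/M, M/G1 and early G1 genes, pheromone response genes, tubulin and tubulin-folding genes, spindle motors and microtubule-associated proteins, kinetochore and spindle checkpoint genes, phosphate starvation, ergosterol synthesis, cytosolic and mitochondrial ribosomal protein, ribosome biogenesis, environmental stress response, meiosis and sporulation, a-specific, α-specific, mitochondrial genome and auxotrophic marker genes. Lists with at least 3 tested members, 19 in number, were compared with other genes by camera with a preset correlation of 0.01, by camera with an estimated correlation and by fry, which tests a list against no change and not against other genes. The pheromone response, a-specific and ribosome biogenesis calls of camera did not hold with an estimated correlation, and these lists passed with fry.

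Genes are named by a fixed rule. SET1, TUB1, TUB2, TUB3, TUB4, CIN8, KAR3, CIK1, MAD2, CLB2, SIC1 and CLN2 are named in every comparison that measured them. For the strain difference, the 8 highest and 8 lowest called genes with that sign in at least 9 of 10 time points are named. For tails, the rule takes up to 5 on each side with at least 100 poly(A) reads on average. Up to 3 members with the largest range in WT are named for 6 lists, the 10 smallest p-values for the profile difference, and the 2 smallest for each list. Other list members are named where a list had few calls, after their values were seen. The groups, tests, lists, naming rule and most alternatives were chosen before the data were examined.

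Each step was tested on simulated data. For the strain difference, 61.2% of genes changed by 1.5-fold, 92.5% of those changed by 2-fold and 90.9% of those changed by 4-fold were recovered among 5041 genes, with 7 unchanged genes called. For change over time in WT, an oscillation of 60 min period was recovered in 0, 2.99% and 34.9% of genes at sizes of 1.5, 2 and 4-fold among 5028 genes, and one of 120 min period in 1.49%, 23.9% and 90.9% among 5022 genes. For the difference of profiles the recovered shares were 0, 0 and 1.52% at 60 min among 5028 genes and 1.49%, 7.46% and 78.8% at 120 min among 5022 genes. For tails, strain differences of 3, 5 and 10 nt were recovered in 22.4%, 52.2% and 90.9% of changed genes among 4281 genes. Changes over time of the same sizes were recovered in 0, 14.8% and 46.0% among 3919 genes. The sign-flip test passed in 5.6% of 500 simulated sets without a shift, 80.2% with a shift of 1 SD and 100.0% with 2 SD. Lags were recovered within 2.5 min in 26 simulated cases of smooth profiles without added noise, which covers the error of interpolation alone.

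Alternatives were DESeq2 size factors, DESeq2 1.42.0, limma-voom, other count minimums, other spline sizes, other poly(A) read minimums, weights and scales for tails, other profile summaries, and leaving out each time point in turn in both strains. Counting poly(A) reads alone, leaving out 105 and 120 min, using the poly(A) share as a covariate and taking the hours separately were added after the data were seen. Transcripts of the mitochondrial genome were left out because they had at most 38 reads in a library. Tables were also handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plotted with matplotlib 3.10.9.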

Results

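Messenger RNA was profiled along the cell cycle of budding yeast in a wild-type strain (WT, the laboratory strain W303a of mating type a) and in a strain lacking SET1. Set1 is the catalytic subunit of COMPASS, the complex that methylates lysine 4 of histone H3. The series sets histone methylation and the toxicity of benomyl, a drug that depolymerises microtubules, beside control of the cell cycle. The libraries analysed here carry no benomyl label. Each strain gave 10 libraries, 1 from an asynchronous culture and 9 taken from 0 to 120 min, every 15 min, after release from arrest in G1 by the mating pheromone α-factor. The assay was PAT-seq, which sequences the 3′ ends of polyadenylated transcripts and gives both a read count and a mean poly(A) tail length per gene. Each strain and time point was represented by 1 library, so values at single times have no replicate error.

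Library depth ranged from 476565 reads (set1Δ, 30 min) to 2413354 reads (WT, 75 min), with a median of 1524255. Between 5654 and 6039 of the 6532 features had a read in a given library. The share of reads with a poly(A) tail ranged from 52.4% to 76.3% in set1Δ. In WT it lay at 91.7% at 30 min, 51.3% at 105 min and 32.2% at 120 min. The WT library of 120 min also had the highest share of reads in its 10 most abundant features, 21.6%, and the lowest scaling factor, 0.621, followed by WT at 105 min with 0.817. Counts over all genes, and the list counts of the strain difference that changed, are therefore also given without 105 and 120 min.

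**Figure D1:**
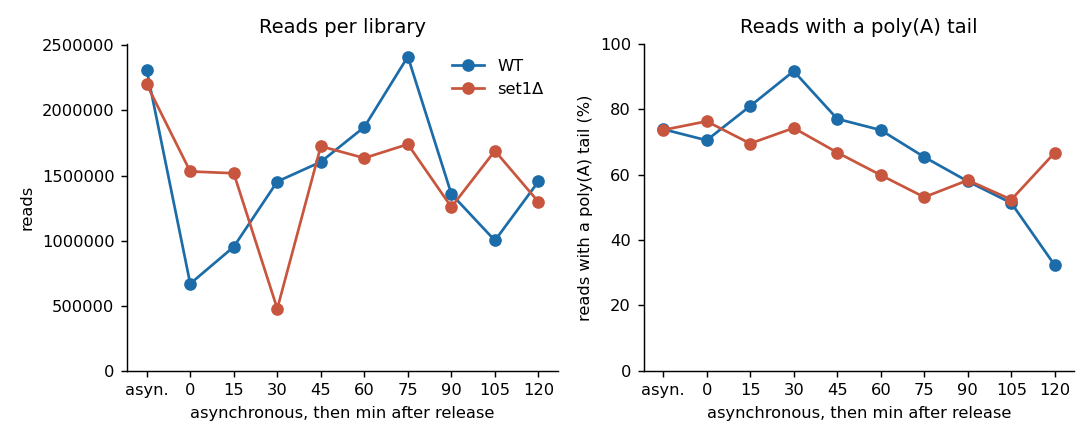
Reads per library (left) and the percentage of reads with a poly(A) tail (right) for WT (blue) and set1Δ (red), in asynchronous culture and from 0 to 120 min after release, 1 library per point. The WT library of 120 min has the lowest poly(A) share, 32.2%.

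SET1 (YHR119W, chromosome VIII, 346043 to 349285, plus strand in assembly R64) was lower in set1Δ at each of the 10 time points. Its level was 44.2 ± 14.6 counts scaled to equal library size (CPM; SD, n = 10) in WT and 9.76 ± 2.81 CPM in set1Δ. WT libraries held 22 to 150 SET1 reads and set1Δ libraries 6 to 35. The log2 difference was −2.16 ± 0.13 (SE; edgeR quasi-likelihood adjusted p = 6.36e-08). The extent of the deletion and the position of the remaining reads were not given in the sources used here, and 3′-end reads from sequence outside the deleted part would check nothing.

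The strains were first compared over the whole time course, which pairs libraries of equal time and not of equal cell cycle position. The lowest transcripts in set1Δ were mostly genes of mating. FIG1 (YBR040W, chromosome II, 316968 to 317864), a membrane protein of mating cells, had a log2 difference of −3.83 ± 0.63 (SE, n = 10 per strain; adjusted p = 7.94e-04, edgeR quasi-likelihood), fitted within time points. Its mean was 364 CPM in WT and 76.9 CPM in set1Δ, less far apart because the set1Δ library of 0 min had 653.8 CPM and no other set1Δ library more than 32.6 CPM. The pheromone-regulated membrane proteins PRM2 (−3.66 ± 0.58), PRM6 (−3.60 ± 0.47) and PRM4 (−3.10 ± 0.38), the a-cell gene ASG7 (−3.54 ± 0.46), the cell-wall adhesins FIG2 (−3.21 ± 0.51) and AGA1 (−3.10 ± 0.48), and the mRNA methyltransferase IME4 (−3.06 ± 0.42) were also lower, each in at least 9 of 10 time points. The exception was the asynchronous pair for FIG1, PRM2, PRM6, ASG7, FIG2 and IME4. There FIG1 had 6.48 CPM in WT and 10.8 CPM in set1Δ, while PRM4 and AGA1 were lower in set1Δ. IME4 is known to have an antisense transcript, and whether the counting used strand was not given in the sources used here, so its value is uncertain.

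The highest transcript was HPF1 (YOL155C, chromosome XV, 28703 to 31606), a cell-wall mannoprotein, at 5.80 CPM in WT and 57.8 CPM in set1Δ, a log2 difference of 3.03 ± 0.34 (adjusted p = 2.86e-05). ARG1 (YOL058W, chromosome XV, 219211 to 220473), an enzyme of arginine synthesis, averaged 17.5 CPM in WT and 85.8 CPM in set1Δ (2.18 ± 0.22, adjusted p = 2.74e-05). Also higher in each of the 10 time points were YHR214W-A (2.32 ± 0.30), IRC18 (2.24 ± 0.25), the putative permease SEO1 (2.15 ± 0.37), the translation factor ANB1 (1.93 ± 0.25) and the cytochrome c gene CYC7 (1.69 ± 0.31), both known for expression at low oxygen, and the sporulation glucoamylase SGA1 (1.64 ± 0.25). Of 5060 genes tested, 427 were higher and 533 lower in set1Δ at an adjusted p below 0.05, of which 195 and 308 differed by at least 1.5-fold and 36 and 109 by at least 2-fold. Without 105 and 120 min the counts were 656 higher and 705 lower, and 380 and 482 of those calls were shared. The number called higher was 680 without 120 min alone, 267 without a term for time, and 700 with the poly(A) share of each library as a covariate, which gave 805 lower.

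Of 24 pheromone response genes, 21 were lower in set1Δ, none was higher, and 23 were lower when adjusted over the list alone. Their median log2 difference was −2.45. In the asynchronous pair 11 were higher and 13 lower in set1Δ, with a median of −0.27. The nuclear fusion genes KAR4 (−2.43 ± 0.30), a transcription factor, and KAR5 (−1.85 ± 0.23) had the smallest p-values of the list. FAR1, which arrests the cycle in G1, had −0.81, the transcription factor STE12 had −0.27 and BAR1, the protease that degrades α-factor, had −1.20, and none of these passed in edgeR over all time points. FAR1 and BAR1 passed in DESeq2 (adjusted p = 0.0255 and 0.0362), which called 23 lower against 21 in limma-voom. With edgeR, FAR1 passed without 60 min (adjusted p = 0.0493) and BAR1 without 0 min (adjusted p = 0.0174). The list lay below other genes with a preset correlation (camera, adjusted p = 7.03e-21), and the adjusted p = 0.385 with an estimated correlation. Against no change, fry gave a shift down (adjusted p = 0.00103). In the series without 105 and 120 min, 20 of the 24 were lower.

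The a-specific genes, expressed in cells of mating type a and partly members of the previous list, were lower in 5 of 7 (7 adjusted over the list alone), with a median of −1.31. ASG7 had −3.54 and the α-factor receptor gene STE2 −1.31 ± 0.25, while the pheromone exporter STE6 (−0.46, adjusted p = 0.0595) and BAR1 did not pass in edgeR over all time points. With poly(A) reads alone STE6 passed (edgeR adjusted p = 0.0212) and BAR1 did not (0.122). All 7 were lower without 0 min, 6 without 120 min and 4 without 105 and 120 min, and DESeq2 called 6 and limma-voom 5. The camera adjusted p was 2.56e-05, and the adjusted p = 0.385 with an estimated correlation, while fry gave a shift down against no change (adjusted p = 0.00609). Of the α-specific genes only SAG1, the agglutinin of α cells, was abundant enough to test. It had 0.45 ± 0.17 (adjusted p = 0.0659), with 1 call when adjusted over the list alone and adjusted p of 0.0389, 0.0459 and 0.0424 without 0, 45 or 120 min.

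Ribosome biogenesis genes were higher in 10 of 31 members tested and lower in 0 (11 and 0 adjusted over the list alone), with a median of 0.29. They were 12 without 105 and 120 min and 7 to 12 over the leave-outs of 1 time point. NOP7 (0.57 ± 0.11) and NOG1 (0.58 ± 0.13), which act in assembly of the large ribosomal subunit, had the smallest p-values. The camera adjusted p was 5.90e-05, and the adjusted p = 0.385 with an estimated correlation, while fry gave a shift up against no change (adjusted p = 0.0253). Of 132 cytosolic ribosomal protein genes 8 were lower and 0 higher, against 0 adjusted over the list alone and 19 lower and 5 higher at an unadjusted p below 0.05 (median −0.06, camera adjusted p = 0.417). DESeq2 called 12 lower and 5 higher and limma-voom 8 and 0. The lower count hung on single time points, with 1 without 60 min, 2 without 75 or 105 min, 3 without 90 min, 5 without 30 or 45 min or the asynchronous pair, 6 without 15 min, 14 without 0 min and 13 without 120 min, when 7 were higher. RPL17B (−0.42 ± 0.11) alone kept its call in each leave-out, while RPS29B (−0.42 ± 0.11) lost it without 60 min (adjusted p = 0.0518). In the series without 105 and 120 min, 6 ribosomal protein genes were higher and 11 lower. Ribosomal protein genes are often paralog pairs, between which the counting could have divided reads, so single members are uncertain. Among 42 mitochondrial ribosomal protein genes 2 were lower, MRPL24 (−0.66 ± 0.16) and MRPL31 (−0.39 ± 0.13), and 1 when adjusted over the list alone (median −0.11, camera adjusted p = 0.176). MRPL31 lost its call in 7 of the 10 leave-outs, asynchronous, 15, 45, 60, 75, 90 and 105 min, with adjusted p from 0.0741 to 0.131. Members lower were 6 without 105 and 120 min or without 120 min alone, 3 without 0 min, and 1 without 15, 45, 60, 75 or 105 min or the asynchronous pair.

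Of 21 environmental stress response genes 4 were lower and 0 higher, also when adjusted over the list alone (median −0.27, camera adjusted p = 0.129). They were the small heat shock proteins HSP42 (−0.90 ± 0.16) and HSP12, the sugar phosphate enzyme PGM2 (−0.90 ± 0.21) and MSC1. Of the 10 leave-outs, HSP12 kept its call only without 0 or 120 min and MSC1 only without 30 or 120 min or the asynchronous pair, with adjusted p up to 0.0649 and 0.108. The lower count of the list was 2 without 15, 45, 60, 90 or 105 min and 6 without 120 min, and 1 gene was higher without 0 min. In ergosterol synthesis 1 of 23 genes was higher and 3 lower, with the same counts adjusted over the list alone (median −0.10, camera adjusted p = 0.532). The sterol enzymes ERG27 (−0.52 ± 0.12) and ERG26 (−0.40 ± 0.12) had the smallest p-values, and ERG26 lost its call without 15, 30, 45, 60 or 75 min, with adjusted p from 0.0557 to 0.0680. In each of these leave-outs ERG27 was the only call of the list, while without 120 min 3 were higher and 6 lower. Of the ergosterol genes 4 were higher and 7 lower without 105 and 120 min.

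Of 9 phosphate starvation genes 0 passed the edgeR test over all genes, and 2 were higher and 1 lower adjusted over the list alone (median 0.14, camera adjusted p = 0.532). At an unadjusted p below 0.05 these counts were also 2 and 1, with 0 and 0 in DESeq2 and 1 and 0 in limma-voom, and 1 was lower without 105 and 120 min. In edgeR 1 was higher without 15, 90 or 120 min. The vacuolar phosphatase PHO8 had 0.43 ± 0.16 (adjusted p = 0.0668, and 0.0203 without 90 min) and the regulator PHO81 −0.56 ± 0.21 (adjusted p = 0.0675, and 0.0488 without 105 and 120 min). Of 3 meiosis and sporulation genes 0 passed the edgeR test, over all genes or over the list alone, 1 was lower at an unadjusted p below 0.05 or without 105 and 120 min, and 0 passed in DESeq2 or limma-voom (median −0.42, camera adjusted p = 0.580). The synaptonemal complex gene ZIP1 had −0.61 ± 0.29 (adjusted p = 0.147, and 0.0275 without 15 min) and the meiotic regulator IME1 −0.42 ± 0.29 (adjusted p = 0.325, and 0.0467 without 105 and 120 min). Of 3 auxotrophic marker genes, LYS2 (1.02 ± 0.13, adjusted p = 7.14e-05) was higher and TRP1 (−0.36 ± 0.12, adjusted p = 0.0427) lower, with the same counts over the list alone. The median of this list was −0.34 although camera gave its direction as up (adjusted p = 0.845). The call of TRP1 was lost in 8 of the 10 leave-outs, asynchronous, 0, 15, 45, 75, 90, 105 and 120 min, with adjusted p from 0.0565 to 0.101. No transcript of the mitochondrial genome was abundant enough to test.

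Microtubule genes were examined because benomyl acts on tubulin. All 4 tubulin genes were higher in set1Δ. The α-tubulin genes TUB1 (YML085C, chromosome XIII, 97941 to 99400) and TUB3 (YML124C, chromosome XIII, 22048 to 23683) had log2 differences of 0.54 ± 0.16 and 0.56 ± 0.13, the β-tubulin gene TUB2 (YFL037W, chromosome VI, 56336 to 57709) had 0.57 ± 0.12 and the γ-tubulin gene TUB4 (YLR212C, chromosome XII, 564860 to 566281) 0.55 ± 0.12 (SE, n = 10 per strain). TUB2 was higher in 10 of 10 time points and the other 3 in 9. The edgeR quasi-likelihood adjusted p was 0.0243 for TUB1, 0.00366 for TUB2, 0.00492 for TUB3 and 0.00513 for TUB4. TUB1 lost its call without 30, 75 or 90 min (adjusted p = 0.0550, 0.0603 and 0.0557). TUB1 and TUB3 are paralogs, so a division of shared reads between them is possible.

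In the whole list of 16 tubulin and tubulin-folding genes 4 were higher and 1, the prefoldin subunit GIM4 (−0.43, adjusted p up to 0.0532 without 60 or 75 min), was lower, against 4 and 3 adjusted over the list alone. The list median was −0.13 while camera gave its direction as up (adjusted p = 0.916), and 2 genes were lower without 105 and 120 min. Over the leave-outs 3 to 4 were higher and 0 to 2 lower. Of 21 spindle motors and microtubule-associated proteins 1 was higher and 2 were lower, also over the list alone. The spindle pole component SPC110 was higher (0.76), a call lost in 6 of 10 leave-outs (15, 30, 45, 75, 90 and 105 min, adjusted p up to 0.0950). The minus-end motor KAR3 (YPR141C) had −1.27 ± 0.21 (adjusted p = 5.61e-04, lower in 9 of 10) and its partner CIK1 (YMR198W) −1.92 ± 0.24 (adjusted p = 6.87e-05, lower in 10 of 10). Both are also known as pheromone-induced genes of nuclear fusion. The motor CIN8 had 0.43 ± 0.26 (adjusted p = 0.266). The list median was 0.02 and camera pointed down (adjusted p = 0.845), and 2 genes were higher without 105 and 120 min or without 120 min alone.

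Of 33 kinetochore and spindle checkpoint genes 1 was higher and 3 were lower, against 1 and 2 adjusted over the list alone. The kinetochore genes SPC25 (−0.88 ± 0.17), HSK3 (−0.79 ± 0.21) and DAD4 (−0.42) were lower and CBF2 (0.52) was higher. The checkpoint gene MAD2 had 0.17 ± 0.12 (adjusted p = 0.314). The list median was 0.01, with camera pointing up (adjusted p = 0.845) and the rotation test fry pointing down (adjusted p = 0.938). Of the 10 leave-outs, DAD4 kept its call only without 0, 15 or 120 min and CBF2 lost it without 15, 30, 60 or 105 min, with adjusted p up to 0.103 and 0.0617. CBF2 was not among the calls without 105 and 120 min, when 0 members were higher and 3 lower. Over the leave-outs 0 to 1 were higher and 2 to 4 lower.

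**Figure D2:**
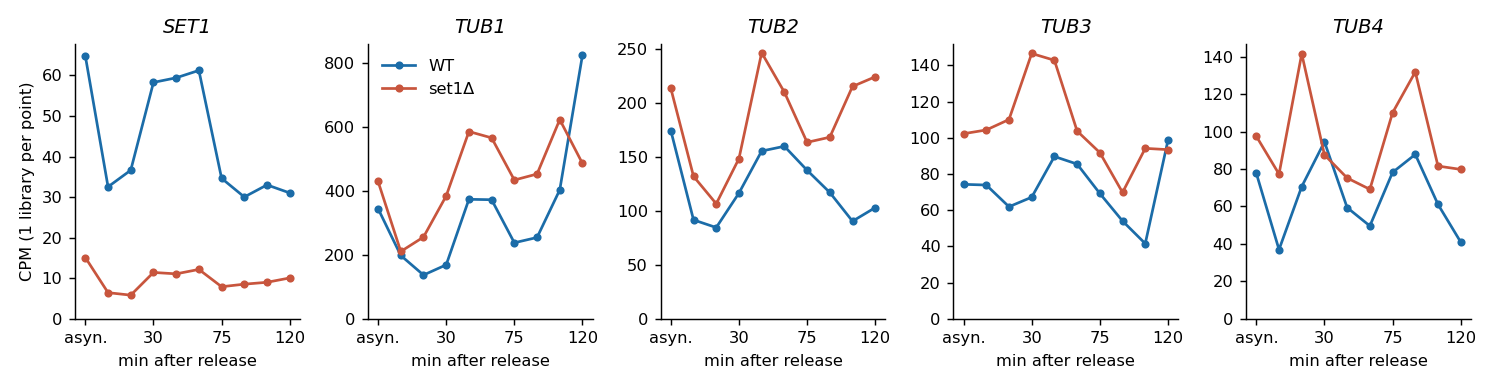
CPM of SET1, TUB1, TUB2, TUB3 and TUB4 in each library, WT in blue and set1Δ in red, from the asynchronous culture (asyn.) to 120 min after release, 1 library per point. SET1 lies at 5.83 to 15.1 CPM in set1Δ and 30.0 to 64.8 CPM in WT.

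In the COMPASS list, SET1 and SHG1 (−0.90) were lower and BRE2 (0.47 ± 0.13) was higher of 7 subunit genes tested, against 1 higher and 3 lower adjusted over the list alone. SHG1 lost its call without 90 min (adjusted p = 0.0621). The median was −0.23 and the camera adjusted p 0.129, while fry gave an adjusted p of 4.41e-05 for a shift of these genes taken alone. SET1 itself is a member of this list.

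Cell cycle lists were compared in mean level between strains. Among 41 G1/S genes 3 were higher and 1 was lower, against 1 and 1 adjusted over the list alone (median 0.09, camera adjusted p = 0.143). The replication protein RFA1 (0.61), the bud-neck kinase GIN4 (0.58) and the checkpoint kinase DUN1 (0.56 ± 0.15) were higher, and the cyclin PCL2 (−1.85 ± 0.24, lower in 10 of 10) was lower. PCL2 had 43.6 CPM in the asynchronous WT culture and 553 CPM at 0 min, against 37.5 and 177 CPM in set1Δ. Whether its difference belongs to the pheromone response was not tested. The G1 cyclin CLN2 had 0.09 ± 0.25 (adjusted p = 0.842). Of these genes 6 were higher without 105 and 120 min. Over the leave-outs 1 (without 75 min) to 7 (without 45 min) were higher, and 1 lower except without 15 min, when 4 were. Of the 10 leave-outs, RFA1 lost its call in 5 (asynchronous, 15, 30, 75 and 105 min) and GIN4 in 4 (0, 60, 75 and 90 min), with adjusted p up to 0.101 and 0.0813.

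Of 9 histone genes 0 passed the edgeR test, over all genes or over the list alone, with 0 also at an unadjusted p below 0.05, in DESeq2 and in limma-voom (median 0.08, camera adjusted p = 0.647). The linker histone HHO1 had 0.27 ± 0.15 and HHT2, an H3 gene, 0.21 ± 0.14. Of 18 G2/M genes 4 were higher and 0 lower, also over the list alone (median 0.17, camera adjusted p = 0.129). They were the bud-site protein BUD4 (0.69 ± 0.17), the myosin MYO1 (0.64 ± 0.18), the transcription factor SWI5 (0.61 ± 0.18) and the chitin synthase CHS2 (0.53). MYO1 lost its call without 45 min (adjusted p = 0.0619), SWI5 without 45, 90 or 105 min (0.0658, 0.0574 and 0.0554), and CHS2 in 5 of 10 leave-outs (asynchronous, 30, 45, 60 and 105 min, up to 0.0780). The higher count was 3 without 105 and 120 min and 1 to 5 over the leave-outs. The mitotic cyclin gene CLB2 had at most 9 reads in a library and was not tested.

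Of 19 M/G1 genes 0 were higher and 5 lower, against 1 and 5 adjusted over the list alone (median −0.33, camera adjusted p = 0.0881). The transcription factor TEC1 (−1.50 ± 0.24) and the chitin synthase CHS1 (−1.41 ± 0.25) had the smallest p-values, beside the cell-wall gene PST1 (−1.52), NIS1 (−1.07) and AMN1 (−1.02). The Cdk inhibitor SIC1 had 0.08 ± 0.16 (adjusted p = 0.766). The counts were 1 higher and 3 lower without 105 and 120 min, and over the leave-outs 0 to 1 higher and 5 to 7 lower. Of 9 early G1 genes 1 was lower, also over the list alone, the cyclin CLN3 (−0.65 ± 0.12, lower in 10 of 10), and the helicase subunit MCM6 had 0.44 ± 0.19 (adjusted p = 0.106, and 0.0255 without 30 min). The median of that list was 0.21 (camera adjusted p = 0.532), and 1 was higher and 1 lower without 105 and 120 min.

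Changes with time after release were tested next, the stated purpose of the series being expression across the cycle. Pheromone response genes changed in 21 of 24 members in WT (23 adjusted over the list alone) and 22 in set1Δ (23), with list medians below the 0 min level at each later time. FUS2, a cell fusion gene, spanned 4.13 log2 units in WT and 5.25 in set1Δ (adjusted p = 1.46e-06 and 6.51e-09), PRM4 4.39 and 5.12, and KAR5 4.09 and 3.93, each highest at 0 min. G2/M genes changed in 16 of 18 in each strain (17 and 18 over the list alone). The cyclin CLB1 spanned 5.36 log2 units in WT and 6.27 in set1Δ (adjusted p = 2.91e-06 and 1.81e-06), and the transcription factor SWI5 (4.14 and 4.57) also changed in both.

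Of 19 M/G1 genes 13 changed in WT and 18 in set1Δ (16 and 19 over the list alone). The cell-separation gene EGT2 spanned 6.15 and 6.05 log2 units, highest at 75 min in both strains (adjusted p = 3.93e-04 and 6.45e-04), PCL9, a cyclin, 4.48 and 7.33, and PRY3 5.18 and 3.76. SIC1 changed in both strains (2.44 and 3.32). Of 41 G1/S genes 17 changed in WT and 23 in set1Δ (21 and 36 over the list alone), and 35 and 38 without 105 and 120 min. The repressor NRM1 (4.13 and 4.06) and the mannosyltransferase MNN1 (4.54 and 3.29) changed in both, the cell-wall protein TOS6 (4.99 and 4.76) passed in WT (adjusted p = 0.0287) and had 0.0551 in set1Δ, and CLN2 (3.13 and 4.80) passed in neither (0.162 and 0.0586).

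Of 9 histone genes 3 changed in each strain (3 and 4 over the list alone), and 9 in each without 105 and 120 min. The H4 gene HHF1 spanned 4.55 and 4.67 log2 units but did not pass (adjusted p = 0.215 and 0.227), nor did the H2B genes HTB2 (3.65 and 4.02) and HTB1 (3.59 and 3.43). Early G1 genes changed in 5 and 6 of 9 (7 and 9 over the list alone). The replication licensing gene CDC6 (4.27 and 2.29) passed in WT (adjusted p = 0.00956) and had 0.136 in set1Δ, MCM3 (2.49 and 2.72) passed in both, and MCM7 (3.03 and 3.25) in neither (0.0749 and 0.105).

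Among the fixed genes, TUB1 and TUB2 changed in both strains, TUB3 and TUB4 passed in WT alone, KAR3, CIK1 and MAD2 changed in both, CIN8 in neither, and SET1 passed in WT alone (adjusted p = 0.0264 against 0.571). Passing in 1 strain alone is not a tested difference between strains. Of 5060 genes, 1977 changed in WT, 795 in set1Δ and 622 in both (edgeR quasi-likelihood, spline of 5 degrees of freedom). Without 105 and 120 min 1265 changed in WT, 1045 of them shared with the full series, and 1013 in set1Δ. With poly(A) reads alone the number in WT was 51.8% of that with all reads, and with 3 degrees of freedom 215 changed in set1Δ. Leaving out 45 min gave 360 in set1Δ, and leaving out 75 min 430. A simulated oscillation of 60 min period and 4-fold size was recovered in 34.9% of genes, so a gene that did not pass was not thereby shown to be constant.

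The difference of time profiles was tested directly. Pheromone response genes differed in profile in 17 of 24 (22 adjusted over the list alone), among them PRM6 (adjusted p = 3.34e-04), FUS2 (3.79e-04), PRM2 (7.42e-04), FIG1 (0.00128), AGA1 (0.00154) and STE2 (0.00269). Without 105 and 120 min the count of this list was again 17, and with poly(A) reads alone 12. At 15 min the median log2 difference of the list from its 0 min value was −1.08 in WT and −3.80 in set1Δ, and at 45 min −1.64 and −4.87. The profile of TUB1 also differed (adjusted p = 0.00769), and those of TUB2 (0.213), TUB3 (0.335), TUB4 (0.570), KAR3 (0.335), CIK1 (0.526), CIN8 (0.780), MAD2 (0.326), SIC1 (0.539), CLN2 (0.50) and SET1 (0.731) did not pass. The call of TUB1 was lost without 105 and 120 min, when 0 of 16 tubulin and tubulin-folding genes differed. TUB1 had 826 CPM in the WT library of 120 min, against 486 CPM in set1Δ.

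The smallest p-values belonged to other genes. FIT2 (YOR382W), a cell-wall protein of iron uptake, spanned 4.38 log2 units in WT and 1.69 in set1Δ (adjusted p = 7.09e-06). The ribosomal protein RPS14B (adjusted p = 1.97e-04, 4.50 and 1.80 log2 units) and the mitochondrial chaperonin HSP60 (adjusted p = 1.97e-04, 2.95 and 1.31) followed. The aromatic amino acid enzyme ARO2, the translation factors TEF4 and FUN12, the phosphatase SHB17, HIF1, RPL43A and the chaperone YDJ1 had adjusted p from 2.32e-04 to 2.41e-04. All 10 had their largest strain difference at 120 min except FIT2, at 105 min. Ribosomal protein genes differed in 42 of 132 (75 over the list alone), and 12 without 105 and 120 min.

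In all, 628 of 5060 genes differed in profile, 396 of them with the largest strain difference at 120 min, the time of the WT library with a poly(A) share of 32.2%. The count was 150 without 105 and 120 min, 84 of them shared, 113 with poly(A) reads alone, 191 without 120 min, 322 without 45 min, 309 without 75 min and 279 with 3 degrees of freedom. Swapping strain labels within time points gave as many genes in 10 of 100 splits, the real one included. Of the named 10, HSP60 (adjusted p = 0.163), ARO2 (0.0886), TEF4 (0.150), FUN12 (0.158), SHB17 (0.0651), HIF1 (0.0914) and YDJ1 (0.306) did not pass without 105 and 120 min. RPS14B (0.576), ARO2 (0.901), TEF4 (0.802), RPL43A (0.115) and YDJ1 (0.714) did not pass with poly(A) reads alone, nor SHB17 (0.107) and HIF1 (0.104) with 3 degrees of freedom. FIT2 passed in each of these.

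The timing of the cell cycle lists was compared by the lag at which the mean profile of set1Δ correlated best with that of WT. G1/S genes were highest at 30 min in WT and at 15 min in set1Δ. Histone genes were highest at 30 min, G2/M genes at 60 min and both M/G1 and early G1 genes at 75 min, in both strains. The set1Δ profile led that of WT by 5 min in the early G1, G1/S, G2/M and M/G1 lists (lag −5 min) and had a lag of −2.5 min in the histone list. Of single genes 38 of 41 in the G1/S list, 18 of 18 in G2/M, 8 of 9 histone, 16 of 19 M/G1 and 7 of 9 early G1 genes were earlier in set1Δ. There was 1 culture per strain, so the lag carries no replicate error and was not tested. Over the leave-outs of 1 time point lags ranged from −7.5 to −2.5 min, and in the M/G1 list the lag of the first hour alone was −30 min, the limit of the search. Leaving out 1 time point moved the lag by more than 1.5 times in the early G1 list (−2.5 min without 30 or 45 min), the G1/S list (−2.5 min without 15 min), the histone list (−5 min without 15, 90, 105 or 120 min) and the M/G1 list (−2.5 min without 0, 15, 60 or 90 min).

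**Figure D3:**
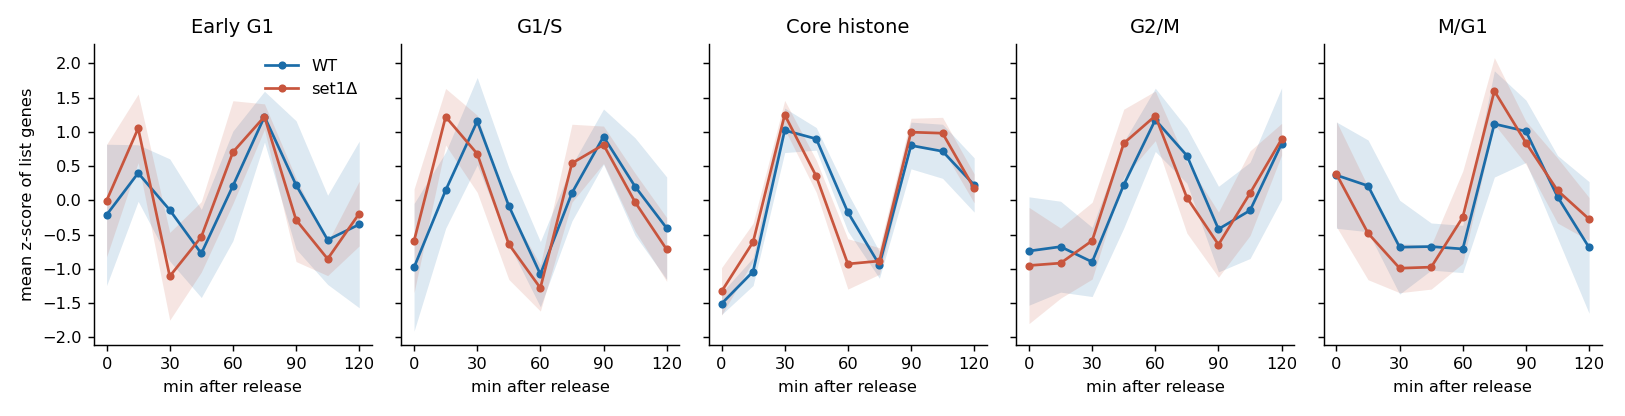
Mean z-score of log2(CPM + 1) over the genes of 5 cell cycle lists against minutes after release, WT in blue and set1Δ in red, with bands of 1 SD over list genes and 1 library per point. G1/S genes peak at 30 min in WT and 15 min in set1Δ.

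The arrest itself was described by the library of 0 min against the asynchronous one, without a test because each was a single library. Pheromone response genes were higher at arrest in 24 of 24 members in both strains, with median log2 differences of 3.83 in WT and 3.29 in set1Δ, above all of 10000 random lists of like expression. Histone genes had −2.87 and −2.32, G2/M genes −1.60 and −1.53 and G1/S genes −1.54 and −0.70, each below all random lists. Environmental stress response genes had 1.33 in WT, with 20 of 21 higher, and −0.29 in set1Δ, with 17 of 21 lower (percentiles 100 and 0.110). Ribosomal protein genes had −0.53 and 0.11, ribosome biogenesis genes −0.66 and −0.03, and a-specific genes 1.09 and 2.47. Set directly against each other at 0 min, set1Δ was lower than WT in 20 of 21 stress response genes (median −1.70) and higher in 29 of 31 ribosome biogenesis genes (median 0.83). In the asynchronous pair the medians were −0.04 and 0.11 for these lists, −0.27 for pheromone response genes and −0.32 for histone genes.

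Poly(A) tails were measured in the same libraries. BAR1, the α-factor protease, had a mean tail of 33.8 ± 4.15 nt in WT and 26.7 ± 4.68 nt in set1Δ (SD, n = 10), a difference of −7.04 ± 1.19 nt (SE; limma adjusted p = 0.0106), shorter in 9 of 10 time points. YDR170W-A differed by −5.78 ± 0.79 nt (adjusted p = 9.97e-04, shorter in 10 of 10), the vacuolar transporter YPQ1 by −5.09 ± 1.29 nt, BNA1, an enzyme of NAD synthesis, by −4.63 ± 0.91 nt, and the Ty1 retrotransposon feature YBL005W-B/YBL005W-A by −4.31 ± 0.99 nt. DIA1 was longer by 5.67 ± 1.21 nt (adjusted p = 0.0279). Tails of SET1, TUB1, TUB2, TUB3, TUB4, KAR3, MAD2, SIC1 and CLN2 did not pass (adjusted p from 0.722 to 0.978), and those of CIN8, CIK1 and CLB2 had too few poly(A) reads.

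Of 4281 genes tested, 2 had longer tails in set1Δ, DIA1 and MIG2 (5.57 nt, named after its values were seen), and 61 had shorter ones (limma, adjusted p below 0.05). Without 105 and 120 min these were 6 and 48, and after subtraction of the library median 2 and 13. The shorter count was 101 on the log2 scale. It was 38 without 0 min, 9 without 15 min, 6 without 30 or 105 min, 34 without 45 min, 24 without 60 or 90 min and 8 without 75 min. The longer count was 0 without 30, 75 or 105 min, 1 without 90 min and 10 without 120 min. DIA1 lost its call without 30, 75, 90 or 105 min (adjusted p = 0.0814, 0.0888, 0.0574 and 0.0548), and BNA1 without 15, 30, 75 or 105 min (0.0501, 0.0680, 0.0653 and 0.0548). YPQ1 (adjusted p = 0.0492) lost it without any of 0, 15, 30, 45, 60, 75, 90 or 105 min (0.0501 to 0.0983), and the Ty1 feature (adjusted p = 0.0346) without 15, 30, 60, 75, 90 or 105 min (0.0515 to 0.0917). Reads of Ty elements come from near-identical copies, and single Ty features are uncertain.

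Of the lists, cytosolic ribosomal protein genes had shorter tails in 14 of 130 members (median −1.44 nt; camera adjusted p = 1.53e-14, and adjusted p = 0.761 with an estimated correlation). That count was 11 without 105 and 120 min, 2 after subtraction of the library median, 0 without 15, 30, 75 or 105 min, 5 without 0, 45 or 60 min, 6 without 90 min, 22 without the asynchronous pair and 19 without 120 min. Camera used members with a value in each library. The a-specific genes were shorter in 2 of 7 (median −2.48 nt; camera on 6 members, adjusted p = 0.00704, and adjusted p = 0.673 with an estimated correlation), and in 1 after subtraction of the library median or in 7 of the 10 leave-outs. Spindle motors and microtubule-associated proteins had 0 of 12 calls and a median of 0.54 nt (camera on 7 members, up, adjusted p = 0.00896, and adjusted p = 0.168 with an estimated correlation).

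The median tail over 3153 genes was 29.6 ± 1.42 nt in WT and 28.9 ± 1.30 nt in set1Δ (SD, n = 10 libraries per strain). The paired difference of −0.682 ± 1.46 nt (SD), negative at 6 of 10 time points, did not exceed its spread (exact two-sided sign-flip permutation test, p = 0.217). It was largest at 30 min (−2.80 nt) and 120 min (−3.82 nt). It was −0.320 nt without 120 min, −0.414 nt without 30 min and −0.283 nt without 105 and 120 min. With at least 30 poly(A) reads per gene it was −0.889 nt (exact permutation p = 0.0273), and weighted by reads −1.15 nt, negative at 10 of 10 (exact permutation p = 0.002, the smallest the test can give).

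**Figure D4:**
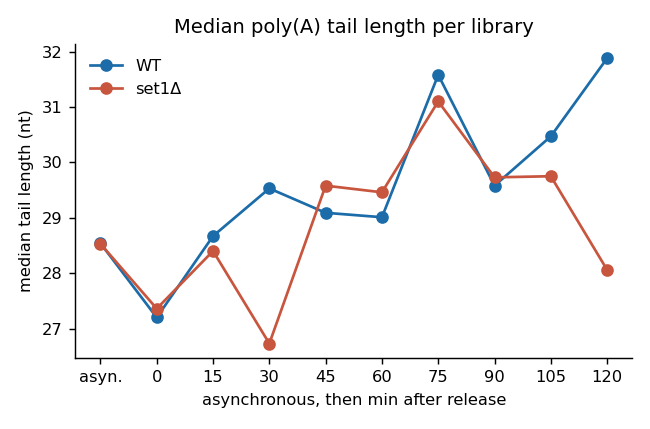
Median poly(A) tail length in nt over 3153 genes per library, WT in blue and set1Δ in red, in asynchronous culture (asyn.) and from 0 to 120 min after release, 1 library per point, with an axis that does not start at 0. The strains differ most at 30 min (−2.80 nt) and 120 min (−3.82 nt).

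Over time, tails of 418 of 3919 genes changed in a profile common to both strains (limma F-test). The ribosomal protein genes RPS7A, RPL3 and RPS21B, longest at 105 min, and the ubiquitin-conjugating enzyme UBC13, longest at 90 min, had the smallest p-values and were named after their values were seen. Ribosomal protein genes changed in 36 of 130 and histone genes in 8 of 9. Tails of the called genes were shortest at 0 min in 199 genes and longest at 75 min in 146. The median tail per library moved likewise, from 27.2 nt in WT and 27.4 nt in set1Δ at 0 min to 31.6 and 31.1 nt at 75 min. These times are therefore not shown to be particular to the called genes. The count was 545 without 105 and 120 min, 205 without 0 min, 271 without 15 min, 243 without 75 min and 275 without 105 min.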

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

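The tests of another mating type and of its equal share, of a later end of the pheromone signal, of reads without a poly(A) tail, of a common offset and of a single deciding time point were chosen after the results were seen, and the rule used to judge thinned reads after its first draw.

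The set1Δ library of 30 min had 5654 features with a read, which set it apart from the other set1Δ libraries relative to their range. It was the only one among 14 groups of libraries examined over 7 measures, and chance marks about 1 in 20 groups. Reads on mitochondrial genome features, which no comparison used, reached 38 in a library.

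Of 86 named genes tested, 25 had a time profile that differed between the strains by the interaction test of edgeR. Since 10 of them were named for the smallest p in this test and others for their strain difference, this share is not that of all genes, 628 of 5060. The adjusted p was 7.09e-06 for FIT2, 0.000197 for RPS14B and HSP60, 0.000232 for ARO2, and 0.000241 for HIF1, SHB17, FUN12, TEF4, YDJ1 and RPL43A. Among mating genes it was 0.000334 for PRM6, 0.000379 for FUS2, 0.000742 for PRM2, 0.00154 for AGA1, 0.00269 for STE2 and 0.00128 for FIG1. It was 0.00583 for KAR4 and 0.0378 for KAR5. It was 0.00398 for IME4, 0.00463 for PGM2, 0.00769 for TUB1, 0.012 for PCL2, 0.0128 for SPC25, 0.0365 for TEC1 and 0.0448 for CHS1. Without 105 and 120 min, 0 of 16 tubulin and tubulin-folding genes and 0 of 33 kinetochore and spindle checkpoint genes differed in profile. The calls of TUB1 and SPC25 were therefore lost in that setting.

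Pheromone response genes were lower in set1Δ after release, by a median of −3.87 log2 units at 45 min. Different cell cycle positions were argued against, since no shift of the WT profile by up to 30 min brought the median of the 24 genes nearer to 0 than −2.21. A share of cells of another mating type equal at all times was argued against. The mean list median of 15 to 120 min minus that of the asynchronous culture and 0 min was −2.28 (SD 0.71 over the 8 later times). A share that varied would have to change within 15 min of 1 culture, since the median difference went from −0.89 at 0 min to −3.14 at 15 min. Each of these times was 1 library per strain. The a-specific genes of the asynchronous pair, of which 5 of 7 were lower (median −0.44, lowest −1.09), cannot tell such a share apart, because that pair was also 1 library per strain. A pheromone signal that ended later in the WT culture cannot be told apart from an effect of the deletion, because there was 1 culture per strain: from 0 to 45 min the median was −1.64 in WT and −4.87 in set1Δ, and the bound set for this test was wrong, since a slower fall of more than 1 log2 unit is still a slower fall. An effect of Set1 on these genes, the difference the design names, stays open beside it and was not tested apart.

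Of 628 genes whose profile differed, 396 had their largest difference at 120 min, where the WT library had a poly(A) share of 32.2%. Reads without a poly(A) tail in the late WT libraries are a candidate explanation for most of these calls, since 113 were left with poly(A) reads alone, 107 of them shared. The lower number of poly(A) reads was argued against as the whole cause, since all reads thinned to that number gave a median of 499 (467 to 535 over 10 draws); this narrowly missed the bound of over 500 set beforehand, and the verdict rests on every draw exceeding 50% of 628, a rule set after the first draw was seen. Swapping strain labels within time points gave as many genes in 10 of 100 splits, the highest with 1134, so chance could not be excluded. A difference in late profiles due to the deletion stays open, untested apart from the libraries.

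The mean profiles of the cell cycle lists ran ahead in set1Δ. A single deciding time point was argued against, since 0 of the 5 lists had a lag of 0 or later in any leave-out. A common offset, such as a release or sampling a few minutes apart, cannot be told apart from a faster cycle, because there was 1 culture per strain and the spread of lags over lists and hours, 5 min without the M/G1 lag at the search limit of −30 min, was as large as the lags themselves. From the first to the second hour the lag went from −7.5 to −2.5 min for G1/S, −5 to −2.5 min for histone and −7.5 to −5 min for G2/M genes. It stayed at −5 min for early G1 genes and went from −30 min, the search limit, to −2.5 min for M/G1 genes. The histone and G2/M changes were no larger than the search step of 2.5 min, which was also the largest error on simulated profiles without noise. These changes therefore cannot tell a constant offset apart from a faster first cycle. A faster first cycle in set1Δ stays open and was not tested.

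For the strain difference, 1 of 100 splits, the real one, gave as many as 960 genes. The highest other split gave 850 and had swapped 1 of the 10 time points. The real labels thus gave more genes than any other split drawn within these cultures, and 1 of 100 is the smallest share that can arise. For tail length the real split gave 63 genes, the highest other 2, and 1 of 100 splits gave as many. Most of the tail calls were lost after subtraction of the library median, and the splits do not separate shifts of whole libraries from shifts of single genes. Neither count covers differences between cultures.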

How the results depend on the processing

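Counting poly(A) reads, leaving out 105 and 120 min, the poly(A) share as a covariate and separate hours were chosen after the data were seen. No named-gene difference changed sign where either setting passed the threshold, and no lag changed sign. Counts of genes cannot reverse, and sign changes of genes that passed in neither setting were not counted. For single named genes 592 values under other settings were labelled the same, 25 weaker and 11 stronger, and over the leave-outs 941, 50 and 9 were. The 592 include list medians of the arrest, which were judged against their spread over genes and not against a threshold. For the main results the causes of the moves below were not tested, except for the lower number of poly(A) reads. All reads thinned to that number gave a median of 499 profile calls, against 113 with poly(A) reads. Thinned reads gave 1592 genes changing over time in WT.

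Genes higher in set1Δ numbered 267 without a time term, 656 without 105 and 120 min and 700 with the covariate, which gave 805 lower, against 427 and 533. Change over time in WT was called in 1265 genes without 105 and 120 min and in 1.0e+03 (51.8%) with poly(A) reads, against 1977, and in set1Δ in 382 and 215 with 4 and 3 degrees of freedom, against 795. Profiles differed in 279 genes with 3 degrees of freedom, 113 with poly(A) reads and 150 without 105 and 120 min, against 628. Tails were longer in 4 genes with weights, 4 on the log2 scale and 6 without 105 and 120 min, against 2, and shorter in 101 on the log2 scale and 13 after subtraction of the library median, against 61.

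Without 105 and 120 min the list counts became 6 G1/S genes higher, 3 M/G1 genes lower, 2 tubulin genes lower, 2 spindle motor genes higher, 4 ergosterol genes higher and 7 lower, 6 cytosolic ribosomal protein genes higher and 6 mitochondrial ribosomal protein genes lower. The COMPASS list passed with fry (adjusted p = 4.41e-05). With an estimated correlation the pheromone response, ribosome biogenesis and a-specific lists did not pass (camera adjusted p = 0.385 each). With fry, against no change, they passed (adjusted p = 0.00103, 0.0253 and 0.00609). The M/G1 lag was −30 min over the first hour. The tail difference over all genes passed with at least 30 poly(A) reads (−0.889 nt) and weighted by reads (−1.15 nt), against −0.682 nt.

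Leaving out each time point gave 329 to 680 genes higher and 394 to 706 lower, 1474 to 2223 changing in WT, 360 to 991 in set1Δ and 191 to 815 with different profiles. Tails were longer in 0 to 10 genes, shorter in 6 to 85 and changed over time in 205 to 465, and the tail difference over all genes was −0.813 to −0.320 nt. Lags ranged from −5 to −2.5 min for early G1, histone and M/G1 genes, −7.5 to −2.5 min for G1/S and −7.5 to −5 min for G2/M genes. Depth was lowest in the set1Δ library of 30 min, with 476565 reads, which limits single values there; its share in these ranges was not tested.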

Other observations

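The genes of the next paragraphs and the test of the asynchronous pair were chosen after the results were seen. The Ty and chromosome-end patterns were noticed in the results, and their tests were set before the test values were known.

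Some genes of amino acid synthesis were higher in set1Δ beside ARG1. HIS4 of histidine synthesis had a log2 difference of 0.84 ± 0.15 (SE, n = 10 per strain; edgeR adjusted p = 9.62e-04) and LYS2 of lysine synthesis 1.02 ± 0.13 (adjusted p = 7.14e-05), each higher at 10 of 10 time points. The following genes of these pathways did not pass in edgeR over all libraries: ARG4 had 0.50 (adjusted p = 0.208), ARG8 0.06 (0.853), CPA1 0.39 (0.0997), HIS1 0.29 (0.102), LYS1 −0.29 (0.0943) and LYS9 −0.23 (0.139). Of 4 genes known to respond to DNA damage, HUG1 had 1.33 ± 0.21 (adjusted p = 4.31e-04), RNR3 0.95 ± 0.18 (adjusted p = 0.00181) and RNR2 0.35 ± 0.09 (adjusted p = 0.0144), while RNR4 had 0.25 (adjusted p = 0.0907, and 0.0294 in DESeq2). CPA1 passed without 15 min, HIS1 without 15 or 120 min and LYS1 and RNR4 without 120 min, and all 4 with poly(A) reads. No list of amino acid, DNA damage or low-oxygen genes was tested.

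Of genes known for expression at low oxygen, AAC3, a mitochondrial ADP/ATP carrier, was higher at 1.42 ± 0.22 (adjusted p = 3.04e-04) beside ANB1 and CYC7. HEM13 (0.34, adjusted p = 0.121), COX5B (−0.02, 0.946), OLE1 (−0.14, 0.529) and TIR1 (−0.03, 0.922) did not pass in edgeR over all libraries, although HEM13 passed without 105 min or with poly(A) reads. The sorbitol dehydrogenase genes SOR1 (1.08 ± 0.19) and SOR2 (1.14 ± 0.20) were higher, and as near-identical copies they share reads. DIA1, whose tail was longer, had a lower level in set1Δ (−2.21 ± 0.22, adjusted p = 2.49e-05, lower at 10 of 10 time points).

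Ty1 retrotransposon features were higher in set1Δ in 30 of 31 and Ty2 features in 7 of 10, while both Ty3 features were lower. Copies are near-identical, so the reads were summed over features. The summed Ty1 and Ty2 level averaged 9426 CPM in WT and 16529 CPM in set1Δ, a mean log2 ratio of 0.81 ± 0.25 (SD over 10 time points), higher in 10 of 10, which argues against a different division of reads between copies. The summed Ty3 level had −1.59 ± 0.64, lower in 10 of 10. Tails of Ty features were shorter in 11 of 41 and longer in 0 (limma), with medians of 21.5 nt in WT and 19.0 nt in set1Δ. The 11 became 1 after subtraction of the library median, and over the leave-outs 0 (without 105 min) to 22 (without 120 min), with 1 without 30 min, 2 without 15 or 75 min and 4 without 60 or 90 min. A difference in the number of Ty copies between the strains was not tested.

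SEO1, SOR1 and SOR2 lie near chromosome ends, and the hypothesis was tested that genes near ends were raised in set1Δ. Of 96 genes within 20 kb of an end, 6 were higher, with log2 differences of 1.08 to 2.15, and 13 lower, with −2.21 to −0.42. Each of the 6 was thus higher by at least 2-fold, as were 36 of all 5060 genes tested. The median of the 96 genes minus that of other genes averaged −0.04 log2 units over 10 time points (exact sign-flip permutation p = 0.123). That direction was opposite to the hypothesis. A median does not show whether a subset of genes near ends was raised, which was not tested. No other distance was tested. Of 207 genes at 20 to 40 kb, which were counted only, 15 were higher and 26 lower.

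Differences set up by the arrest and release alone should leave the asynchronous pair at random signs. Of 907 genes called from the 18 libraries after release, 718, or 79.2%, had the same sign in the asynchronous pair. The share was 88.7% for genes higher and 71.8% for genes lower in set1Δ, against 57.1% of 21 called pheromone response genes. The differences were smaller in the asynchronous pair, with medians of 0.32 against 0.61 after release for genes higher and −0.21 against −0.69 for genes lower in set1Δ. The arrest and release alone are argued against as the source of all signs, not of the size of the differences, and the asynchronous pair was 1 library per strain.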
